A study of Mus musculus with 18 samples.

How the data were processed

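The samples are C2C12 cells, a mouse myoblast line that leaves the cell cycle and turns toward muscle when serum is lowered. Cells received an RNAi against STAC3 or a high-GC control RNAi, and RNA was put on Illumina mouse bead arrays. There are 18 arrays of 15 biological samples: 3 control samples at day 0 (replicates 2, 3 and 4) and 4 samples in each of the other 3 groups. Control day 0 replicate 4, control day 1 replicate 3 and STAC3 RNAi day 1 replicate 1 have a repeat array. Each repeat was averaged with its partner, so that every sample counts once.

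The deposited non-normalized table gives an average bead intensity for 45281 probes on each array, together with a detection p-value for each probe, per the file headers. The authors' value table gives 24538 of these probes on a log2 scale after normalization with lumi, per the submitters' processing notes. The lumi version and settings are not given in the sources used here. The log2 unit was read from the values: between the 90th and 99th percentiles they change by 0.977 to 1.02 for each unit of log2 intensity. Between the 25th and 50th percentiles they change by only 0.542 to 0.712. Fold changes of dim genes in that table are therefore smaller than on the intensity scale. The value at which probes pass a detection p-value of 0.01, called the detection level here, is 6.88.

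The analysis laid down beforehand took the non-normalized table, matched columns to samples by column name, and used background correction with negative controls and quantile normalization. That fit called 0 probes at an adjusted p below 0.05 in both comparisons of RNAi with control and in control differentiation. The table was then checked. Each of its columns has the same ranking of probes as exactly 1 column of the value table (rank correlation 1, with the next column at 0.958 or lower), but for 12 of 18 columns the names differ. In the value table each repeat array is most like its named partner of all 17 other arrays (r of 0.9949, 0.9955 and 0.9956). In the non-normalized table the partner comes 12th, 4th and 17th (r of 0.9706, 0.9893 and 0.9667). The results in the report therefore use the authors' value table, which had been laid down as an alternative. This choice was made after the first fit had been seen. It rests on the repeat arrays and not on the number of genes called, and no column was reassigned by its values. The repeats bear only on their partners among the 12 columns, which are the first arrays of the repeated samples. The names of the rest of the 12 are not checked by them. The values from the first fit stand in the closing section.

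Probes with a detection p-value below 0.01 on at least 3 arrays were kept. The detection p-values were matched to the value table by probe and counted over all arrays, so column names play no part. The rule laid down counted samples in place of arrays, which would need the column names of the non-normalized table. The filter left 18408 probes, of which 15954 carry a single gene name, covering 10146 genes. Of all 24538 probes, 20685 have 1 gene name, 8 have several and 3845 have none. A linear model over the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated t-tests and Benjamini-Hochberg adjustment over the 18408 probes. An adjusted p below 0.05 is called a pass. Values are log2 fold changes with their standard error (SE). Where a gene has several probes, the probe with the highest mean over all samples stands for it.

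Genes are named by a rule laid down before the values were seen. It takes the 10 largest rises and 10 largest falls among passing genes whose groups do not overlap on each day (5 and 5 in the other comparisons), the strongest members of each passing list, and Stac3, Myod1, Myog, Myh3, Mef2c, Ckm, Cdkn1a, Mki67 and Myf5 whatever their values. Myh3 and Mki67 have no named probe in the table used, and the Myf5 probe was detected on fewer than 3 arrays. List members that stand alone against their list are also named, and these were picked after their values were seen.

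There are 25 gene lists, written from textbook knowledge before the data were seen: myogenic regulators, sarcomere, excitation-contraction coupling, myoblast fusion and adhesion, neuromuscular junction, muscle energy metabolism, DNA replication and S phase, G2/M and mitosis, cell cycle exit, progenitor state with Notch and Id genes, IGF axis, extracellular matrix, interferon response, inflammation and chemokines, ER stress and amino acid response, p53 targets, immediate early genes, heat shock proteins, cholesterol synthesis, glycolysis and hypoxia, RNAi machinery, and markers of smooth muscle, adipocytes, bone cells and fibroblasts. A list's shift is the median log2 fold change of its members. Lists were tested with camera, which ranks a list against all other genes, at its preset correlation of 0.01 between genes. They were tested again with the correlation estimated from the data. That setting also takes fewer degrees of freedom for the test, so a pass can be lost without correlated genes. For fibroblast markers under RNAi at day 1 the estimate was -0.033, yet the camera p went from 0.0136 to 0.0252. Adjusted p values of lists are over the 25 lists of a comparison. For members of lists that passed, calls adjusted over the list alone are given beside calls adjusted over all probes. For most other lists only the latter are given.

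The arrays fall into 2 sets by raw intensity. The lowest intensity on an array is 32.1 to 36.0 in a set of 6 and 44.0 to 52.1 in a set of 12. The sets cross all 4 groups. The set of 6 is also the 6 arrays whose names match in both tables, and the set of 12 is the 12 whose names differ, so results within the 12 rest on the names of the value table. Each comparison was repeated with the set as a block and within each set. The block fit took all 18 arrays with the sample as a random block, and its lists were tested from the fitted t-values. Over all comparisons it lost 3 of 43 list calls and gained 3. The same fit without the set lost 4 and gained 2. A list pass that changes with the block need not be due to the set. The set of 6 holds 1 sample of each group at day 0 and 2 of each at day 1.

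The scripts were tested on simulated data with the same design, in which 50 of 18408 probes were changed at each size. For a log2 change of 0.25, 0.5, 1 and 2 the day 0 comparison called 17, 40, 47 and 50 of them with 15 false calls. The day 1 comparison called 15, 44, 49 and 50 with 6 false calls, and the difference between days called 0, 24, 45 and 50 with 7. Control differentiation called 12, 39, 50 and 50 with 14 false calls, and differentiation of RNAi cells 17, 43, 50 and 50 with 7. In 20 simulated day 1 comparisons a list of 25 genes shifted by 0.3 was called in 20, and 1 unshifted list was called. The simulated genes varied independently of each other, while the correlation estimated for the sarcomere list is 0.471. False calls for lists of correlated genes were therefore not tested. A reversal slope of -0.5 put into simulated data came back as -0.46.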

Results

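Genome-wide RNA levels were measured in C2C12 myoblasts at day 0, 24 h after transfection and still in growth medium, and at day 1, 48 h after transfection and after a day in differentiation medium. On each day cells with RNAi against STAC3 were set against cells with control RNAi. Medium and time after transfection change together between the days, so their effects cannot be told apart. Differentiation stands below for both. A difference of the RNAi effect between days likewise mixes medium with time since the RNAi. There are 3 control samples at day 0 and 4 samples in each other group. Stac3 encodes a protein of the calcium channel complex that couples membrane excitation to contraction in skeletal muscle. Between 15146 and 16802 probes were detected per array, and array medians of the authors' values run from 7.19 to 7.194. The labels call the replicates biological samples but do not say whether they came from separate transfections, so p-values measure only the spread between these samples of 1 cell line. With 3 or 4 samples per group, small effects are estimated with low precision. The labels name a single RNAi against STAC3, so what its sequence does to other transcripts was not tested.

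The first question is whether Stac3 RNA was lowered. Stac3 fell at day 0 from 7.06 ± 0.09 (SD, n = 3) to 6.73 ± 0.05 (SD, n = 4), a log2 fold change of -0.33 (SE 0.09, limma adjusted p = 0.0214, exact p = 0.0286 over 35 splits). At day 1 it fell from 7.68 ± 0.21 (SD, n = 4) to 6.75 ± 0.05 (SD, n = 4), or -0.93 (SE 0.08, limma adjusted p = 6.03e-07, exact p = 0.0286 over 70 splits). Every RNAi sample lies under every control sample of its day: day 0 controls at 7.04, 6.98 and 7.15 against 6.70, 6.68, 6.785 and 6.745, day 1 controls at 7.53, 7.69, 7.52 and 7.97 against 6.74, 6.74, 6.70 and 6.81. All 8 RNAi samples are under the detection level of 6.88, so the falls are at least 1.13-fold at day 0 and at least 1.73-fold at day 1. In control cells Stac3 rose by 0.62 from day 0 to day 1 (limma adjusted p = 4.26e-05), while in RNAi cells the difference of 0.02 between days did not pass (limma adjusted p = 0.878). The day 0 fall is the less secure: it did not pass within the set of 12 arrays (-0.295, adjusted p = 0.0671), and with control replicate 4 left out it was -0.28 (adjusted p = 0.101).

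**Figure D1:**
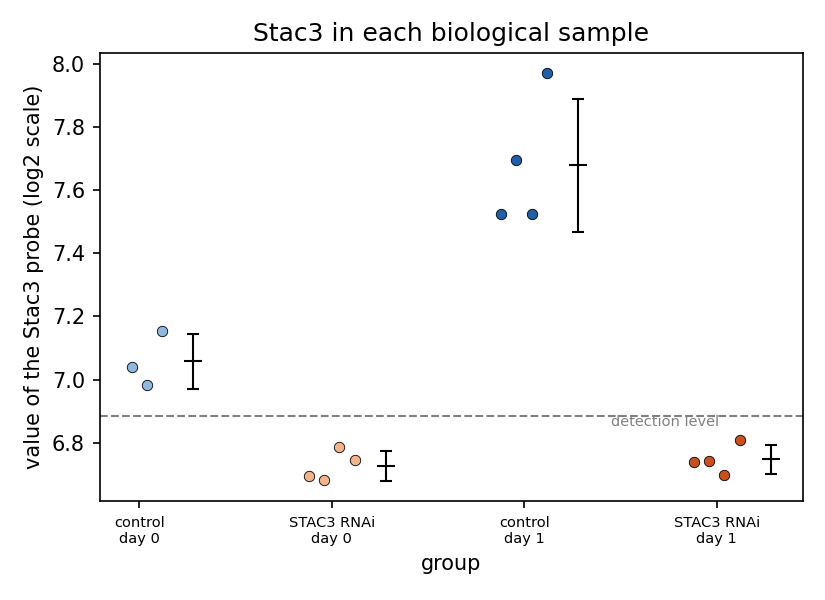
Stac3 RNA in each sample (log2 value of the authors' table) by group, with group mean and SD. The dashed line is the detection level, under which all RNAi samples lie.

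Across all 18408 probes the samples fall into their 4 groups. The leading principal component, with 56.7% of the variance, separates day 0 from day 1, and RNAi samples lie lower on it than controls on both days. The next component, with 21.6%, separates RNAi from control cells, more widely at day 1. The one after (5.62%) sets STAC3 RNAi day 1 replicate 4 apart at -21.1.

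**Figure D2:**
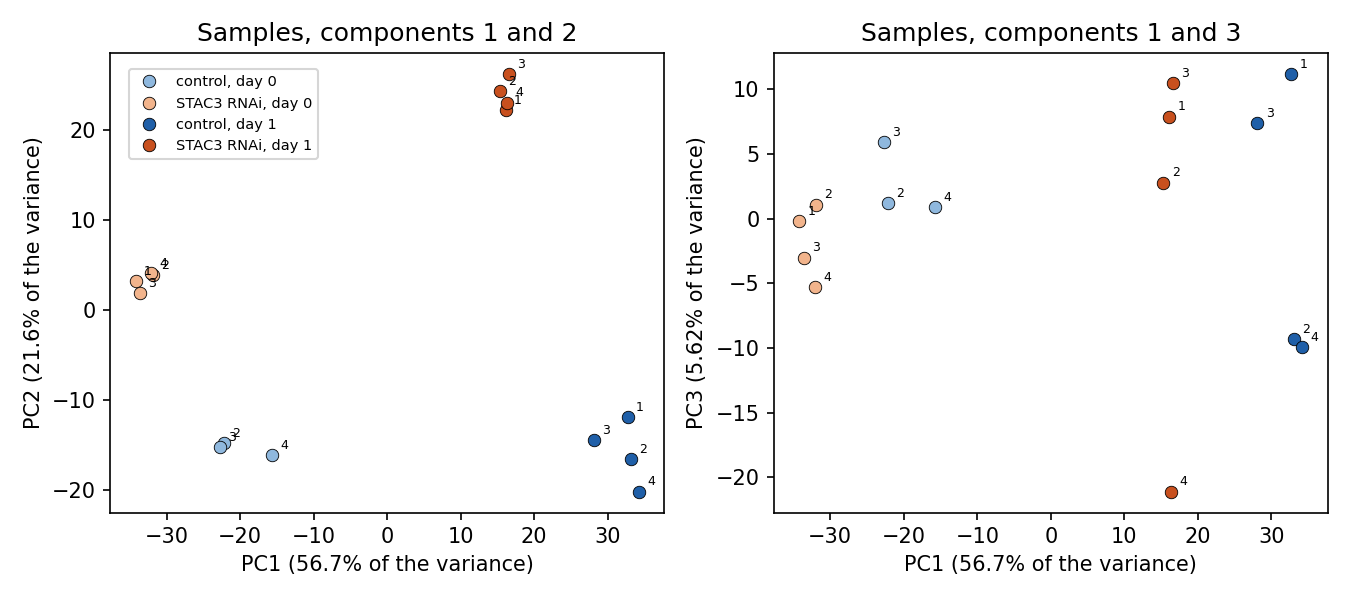
Principal components of all tested probes, 1 point per sample with its replicate number. Axes are component scores; colours are the 4 groups, which do not mix.

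What changed in control cells between day 0 and day 1? Genes of the contractile apparatus rose and genes of the cell cycle fell. The fast myosin light chain Mylpf rose by 3.97 (SE 0.54), the small proteoglycan gene Dcn by 3.96 (SE 0.25), the Z-disc gene Pdlim3 by 3.81 (SE 0.35), the calcium buffer Pvalb by 3.73 (SE 0.32) and fast troponin C, Tnnc2, by 3.67 (SE 0.39; n = 3 and 4, largest adjusted p = 3.06e-05). The 5 largest falls were histone H2A genes: H2ac15 at -3.04 (SE 0.13), H2ac12 at -2.88 (SE 0.15), H2ac22 at -2.77 (SE 0.14), H2ac7 at -2.63 (SE 0.10) and H2ac20 at -2.59 (SE 0.13; largest adjusted p = 1.98e-09). These genes are nearly identical in sequence, so values of single members are uncertain, and the 1 other probe of H2ac20 has the opposite sign. Myog, the regulator that starts terminal differentiation, rose by 2.29 (SE 0.26), the cell cycle inhibitor Cdkn1a by 1.15 (SE 0.09), and muscle creatine kinase, Ckm, at least 2.97-fold from a day 0 level under detection. In all 6599 of 18408 probes passed, 3267 rising and 3332 falling. They include 2100 and 1940 named genes. At least 2-fold changes number 266 up and 290 down.

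Of 34 measured sarcomere genes 29 rose and 1, Tpm3, fell, with the same counts adjusted over the list alone; the median was 1.17 (camera adjusted p = 4.04e-12; adjusted p = 0.179 with an estimated correlation). Among them Actn3, the fast-fibre actinin, rose by 2.454. Genes of energy metabolism in muscle rose in 12 of 17, 12 adjusted over the list alone (median 0.71, adjusted p = 1.09e-06; 0.0517 with an estimated correlation), with Cox7a1 at 1.02 and Ckb at 1.24. Excitation-contraction coupling genes rose in 10 of 22 (10 adjusted over the list alone), with a median of 0.19, and none fell (adjusted p = 0.000571; 0.132 with an estimated correlation), Hrc by 1.48 and the channel subunit gene Cacng1 by 1.16. At the neuromuscular junction 6 of 11 rose (6 adjusted over the list alone) with a median of 0.62 (adjusted p = 0.000548; 0.179 with an estimated correlation), led by the fetal acetylcholine receptor subunit Chrng at 3.43. The IGF axis rose in 9 of 19 genes (9 adjusted over the list alone; median 0.27, adjusted p = 0.0206; 0.0794 with an estimated correlation), among them Igfbp5 by 0.77 and the ubiquitin ligase Fbxo32 by 1.18. Cholesterol synthesis rose in 13 of 18, 17 adjusted over the list alone (median 0.61, adjusted p = 8.9e-05; 0.427 with an estimated correlation), such as Fdps by 0.97.

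Replication genes fell in 28 of 30, 28 adjusted over the list alone, with a median of -1.18 (adjusted p = 3.35e-19; 0.0517 with an estimated correlation): the replicative helicase gene Mcm5 at -2.25 and the flap nuclease Fen1 at -1.76. The 2 that rose are the transcription factors E2f1 (0.61) and E2f2 (0.545). Mitotic genes fell in 22 of 24, 22 adjusted over the list alone (median -1.64, adjusted p = 3.94e-17; 0.0517 with an estimated correlation), Aurka at -2.12 and Cdc20 at -2.14. The 1 that rose, Kif23 at 0.59, has 2 other probes, which both fell. The ER stress and amino acid list fell in 19 of 27, 20 adjusted over the list alone (median -0.46, adjusted p = 1.37e-06; 0.0517 with an estimated correlation), through the serine and asparagine enzymes Phgdh (-1.55), Shmt2 (-1.28) and Asns (-1.18), while its member Vldlr rose by 1.39. Glycolysis genes rose in 12 of 21 and 1, Vegfa, fell, with 12 and 1 adjusted over the list alone (median 0.29, adjusted p = 0.029; 0.516 with an estimated correlation), for instance Aldoc by 1.64. No list kept its pass with an estimated correlation, and the other 15 lists did not pass, though cell cycle exit did with the array set as a block (0.19, adjusted p = 0.0394).

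For control differentiation 7071 probes passed with the array set as a block and 6743 within the 12 arrays. None of these that also passed over all arrays changed sign. The 6 arrays hold 1 day 0 control sample, replicate 4. Among day 0 controls it has the highest means of sarcomere (-0.262) and neuromuscular junction (-0.183). That alone can make the shifts of these lists smaller within the 6. The list shifts under block, 12 and 6 arrays were: sarcomere 1.13, 1.15 and 0.84; energy metabolism 0.69, 0.68 and 0.78; excitation-contraction coupling 0.185, 0.22 and 0.21; neuromuscular junction 0.65, 0.82 and 0.34. For the IGF axis they were 0.26, 0.24 and 0.22 (not passing within the 6), for cholesterol synthesis 0.57, 0.63 and 0.48, for replication -1.16, -1.16 and -0.98, and for mitosis -1.58, -1.59 and -1.26. ER stress gave -0.48, -0.48 and -0.42, and glycolysis 0.265, 0.23 and 0.17, which passed only within the 12 arrays (adjusted p = 0.0868, 0.0415 and 0.108).

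The day 0 comparison asks what STAC3 RNAi changed in growing myoblasts, before differentiation medium. The aminopeptidase-like gene Rnpepl1 rose by 1.84 (SE 0.09) and H2ax, the histone variant marked at DNA breaks, by 1.78 (SE 0.11). The cell cycle regulators Tfdp1, by 1.41 (SE 0.09), and its partner E2f1, by 1.18 (SE 0.07), rose too, and so did the gap junction gene Gja1 by 1.54 (SE 0.20; n = 3 and 4). The other large rises were Ccdc124 (1.44, SE 0.13), Abhd17a (1.43, SE 0.17), the protease inhibitor Timp2 (1.36, SE 0.10), the transcription factor Nfic (1.35, SE 0.12) and the iron-sulfur scaffold Iscu (1.20, SE 0.09). The largest falls were Bcap29 (-1.505, SE 0.08), the cytoskeletal Septin2 (-1.42, SE 0.09), the urokinase gene Plau (-1.35, SE 0.16), the chemokines Ccl7 (-1.32, SE 0.17) and Ccl2 (-1.19, SE 0.18), the GTPase Rhoc (-1.32, SE 0.14), Mrps24 (-1.31, SE 0.09), Prmt3 (-1.27, SE 0.10), the TGF-beta receptor Tgfbr1 (-1.20, SE 0.07) and Elovl1 (-1.18, SE 0.08). Adjusted p for these 20 genes is 0.000479 or lower, and every RNAi sample lies beyond every control sample. In all 2298 probes passed (12.5%), 1233 up and 1065 down. They include 816 and 673 named genes, and 21 and 30 reach 2-fold. The array set as a block gave 2782 and the 12 arrays alone 2779, with no change of sign among probes that also passed over all arrays. Leaving out control replicate 4 gave 1480.

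Among gene groups, DNA synthesis stands out at day 0. Of 30 replication genes 24 rose and none fell, 27 and 0 adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.69e-19; adjusted p = 0.159 with an estimated correlation). Mcm5 rose by 1.09 (SE 0.11), thymidine kinase Tk1 by 0.99 (SE 0.11) and cyclin E2, Ccne2, by 0.89 (SE 0.09). Mitotic genes rose in 11 of 24 and 1 fell, 11 and 1 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.000211; 0.614 with an estimated correlation): Aurkb by 0.45 (SE 0.09), Bub1b by 0.40 (SE 0.09) and Ccnf by 0.27 (SE 0.05). The 1 fall is Kif23 at -0.77 (SE 0.14), of whose 2 other probes 1 rose. Replication genes shifted by 0.52 with the array set as a block, 0.535 within the 12 arrays and 0.64 within the 6. For mitotic genes the shifts were 0.29, 0.285 and 0.31.

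Muscle gene lists did not pass at day 0 in the model of the 4 groups alone. Of 34 sarcomere genes 1 rose and 2 fell (median -0.07, adjusted p = 0.368), and of 15 myogenic regulators none passed (-0.048, adjusted p = 0.761). Myog (-0.20, SE 0.26, adjusted p = 0.698), Myod1 (0.22, SE 0.13, adjusted p = 0.327) and Mef2c (-0.048, adjusted p = 0.748) did not pass, and Ckm (-0.031, adjusted p = 0.94) lay under detection in both groups. Cdkn1a fell by 0.33 (SE 0.09, adjusted p = 0.0194), a call lost when any of 3 single samples is left out. The remaining lists had medians from -0.189 (neuromuscular junction) to 0.158 (RNAi machinery, 3 of 12 up and 1 down), each with an adjusted p of 0.0633 or higher. Energy metabolism had 4 of 17 genes down and none up, 5 and 0 adjusted over the list alone (-0.039, adjusted p = 0.0633). With the replicate number as a block, energy metabolism, inflammation, ER stress and glycolysis passed too, all downward. List means are lower in every RNAi sample than in every control for energy metabolism, the neuromuscular junction, fusion and adhesion, cell cycle exit, inflammation, ER stress and p53 targets, and higher for RNAi machinery, a separation that 2 of 35 splits of the samples give by chance for any list. Of these the inflammation list passed in the fit with the array set as a block, whose list test also differs (-0.105, adjusted p = 0.00443, against -0.112 and 0.0633). For fusion and adhesion the median is 0.017 but the mean is -0.089, and for fibroblast markers 0.005 and -0.038.

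The day 1 comparison asks what STAC3 RNAi changed once cells were differentiating. Muscle genes made up most of the largest falls. Pvalb fell by 3.85 (SE 0.30), with 3 of 4 RNAi samples under the detection level, and so did Chrng (-2.66, SE 0.27), slow troponin T, Tnnt1 (-2.49, SE 0.34), Mylpf (-2.43, SE 0.50), Tnnc2 (-2.20, SE 0.36), Actn3 (-2.03, SE 0.12) and myoglobin, Mb (-2.02, SE 0.28; n = 4 and 4). Outside muscle the falls were the metabolic hormone gene Fgf21 (-2.69, SE 0.10), the secreted C1qtnf3 (-2.19, SE 0.36) and Nme7 (-2.16, SE 0.15), of whose 6 other probes 1 has the opposite sign. Rises were led by Fam180a at 2.29 (SE 0.12), 4.89-fold, Ugt1a10 at 2.00 (SE 0.29), the secreted Fstl1 at 1.93 (SE 0.16), the tubulin regulator Stmn2 at 1.84 (SE 0.17) and Mgst1 at 1.80 (SE 0.20). Timp2 (1.76, SE 0.09), Rnpepl1 (1.73, SE 0.08), Gja1 (1.66, SE 0.18), Acot1 (1.57, SE 0.12) and the early response factor Egr2 (1.496, SE 0.11) follow. Adjusted p for these 20 genes is 0.00151 or lower and no RNAi sample overlaps a control sample.

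Of the genes that drive differentiation Myog fell by 1.47 (SE 0.24, adjusted p = 0.000229) and Cdkn1a fell by 1.13 (SE 0.08, adjusted p = 9.99e-08) at day 1. Ckm fell by 1.49 (SE 0.16, adjusted p = 5.5e-06). Myod1 fell by 0.38 (SE 0.12, adjusted p = 0.0291), a call lost within the 12 arrays (-0.41, adjusted p = 0.0588), and Mef2c did not pass (-0.012, adjusted p = 0.918). In all 6090 probes passed (33.1%), 3100 up and 2990 down, with 2023 and 1809 named genes. At least 2-fold changes number 110 up and 182 down. The array set as a block gave 6544, the 12 arrays 5774 and the 6 arrays 1929, again with no change of sign among probes that also passed over all arrays.

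**Figure D3:**
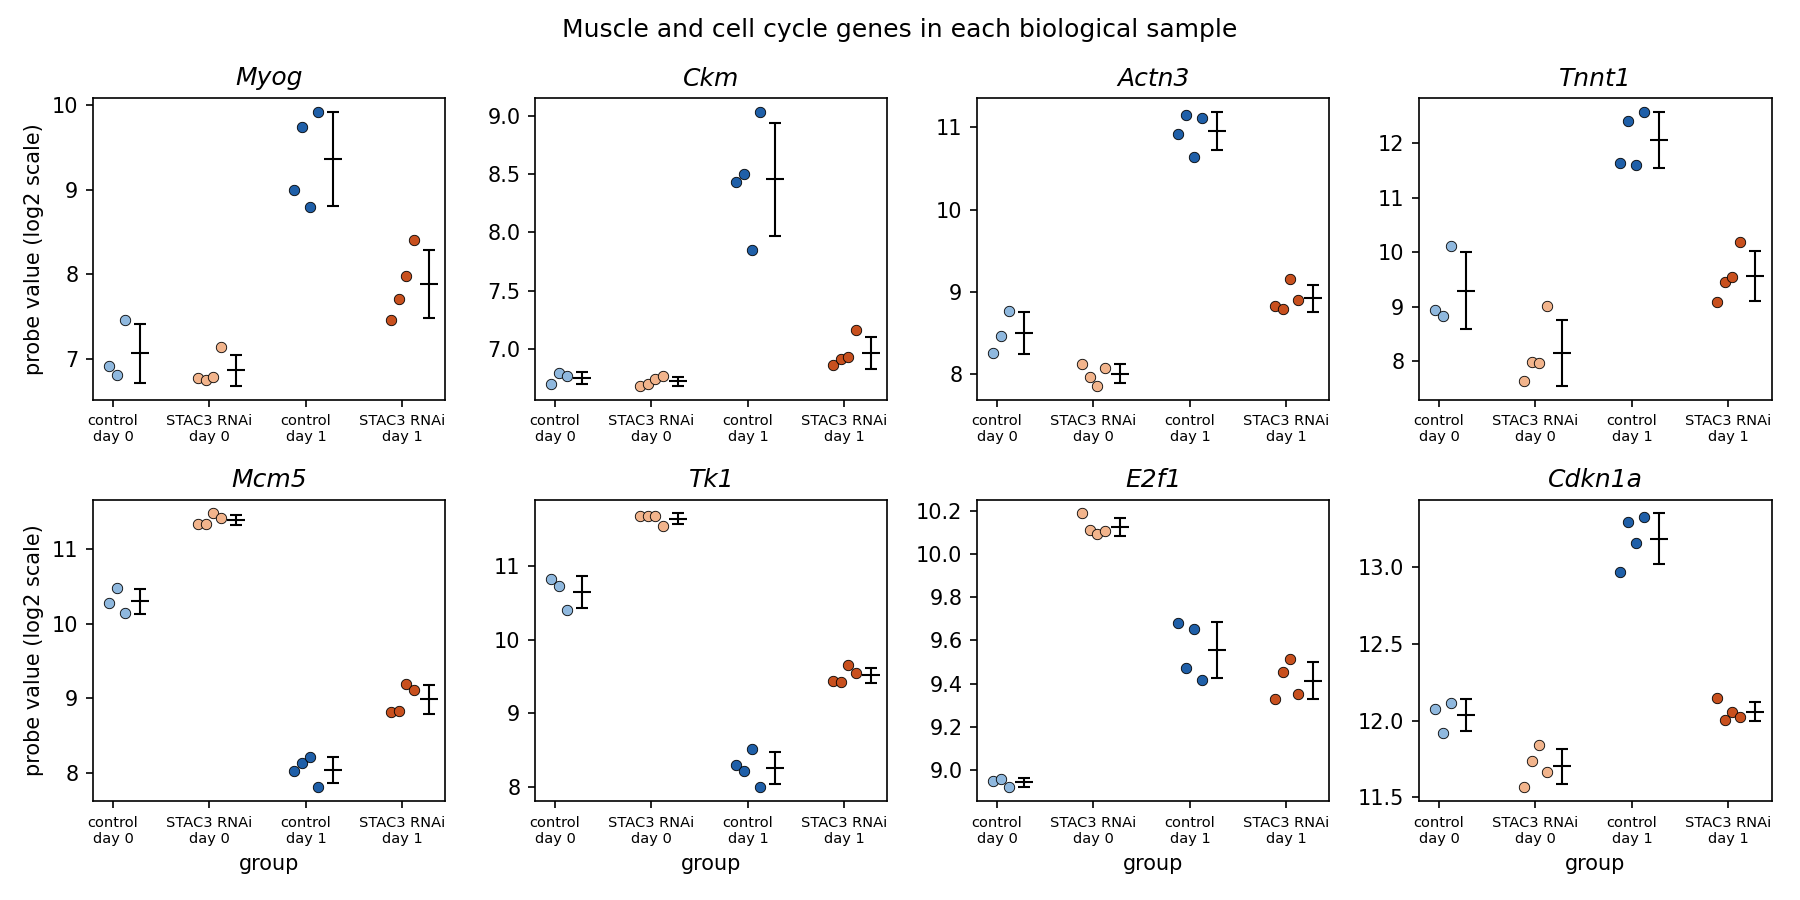
Myog, Ckm, Actn3, Tnnt1, Mcm5, Tk1, E2f1 and Cdkn1a in each sample (log2 value of the authors' table), with group mean and SD. The muscle genes differ between RNAi and control at day 1, and E2f1 at day 0.

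Of 34 sarcomere genes 24 fell at day 1 and 1, Tpm3, rose, 28 and 1 adjusted over the list alone; the median was -0.81 (camera adjusted p = 4.82e-09; adjusted p = 0.312 with an estimated correlation). Csrp3, a Z-disc sensor, fell by 1.26 (3 of 4 RNAi samples under detection), and troponin T3, Tnnt3, fell by 1.23. Energy metabolism fell in 12 of 17, 13 adjusted over the list alone (-0.735, adjusted p = 2.14e-07; 0.132 with an estimated correlation), with muscle enolase Eno3 at -1.35 (SE 0.09) and Cox7a1 at -1.01. In excitation-contraction coupling 12 of 22 fell and 3 rose, the same adjusted over the list alone (-0.20, adjusted p = 0.00205; 0.291 with an estimated correlation): the calcium-store genes Hrc at -1.43 (SE 0.12), Jsrp1 at -0.64 and Asph at -0.58, against rises of Stac2 (0.68), Jph2 (0.455) and Fkbp1a (0.31). Glycolysis genes fell in 14 of 21 and 1, Ndrg1, rose, 15 and 1 adjusted over the list alone (-0.41, adjusted p = 1.59e-05; 0.31 with an estimated correlation), among them the glucose carrier Slc2a1 (-1.37, SE 0.17) and Pkm (-0.65). ER stress genes fell in 8 of 27 and 3 rose, unchanged when adjusted over the list alone (-0.128, adjusted p = 0.0477; 0.373 with an estimated correlation), with Vldlr (-1.14), Psat1 (-0.98) and Asns (-0.54) down and Eif4ebp1, Nupr1 and Sesn2 up.

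Cell cycle genes were higher in RNAi cells at day 1. Mitotic genes rose in 19 of 24 and 1, Kif23, fell, 20 and 1 adjusted over the list alone (0.54, adjusted p = 6.38e-06; 0.312 with an estimated correlation): Bub1b by 0.93 (SE 0.08), Aurka by 0.70 and Aurkb by 0.59. Both other probes of Kif23 (-0.97, SE 0.13) rose. Replication genes rose in 14 of 30 and 1, E2f2, fell, 15 and 1 adjusted over the list alone (0.225, adjusted p = 0.00219; 0.525 with an estimated correlation), Tk1 by 1.26 (SE 0.10) and Mcm5 by 0.94 (SE 0.10). E2f1 did not pass (-0.144, adjusted p = 0.0965), and its change between days passed (-1.33, SE 0.09, adjusted p = 5.01e-06). Fibroblast markers rose in 6 of 11, also adjusted over the list alone (0.28, adjusted p = 0.0477; 0.261 with an estimated correlation): Pdgfra by 0.93 (SE 0.07), Dpt by 0.92, Cd34 by 0.61, Mfap5 by 0.50, Vim by 0.47 and Pi16 by 0.28. The fibroblast and ER stress calls are the weakest of the 8, and both are lost when some single samples are left out.

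List shifts at day 1 with the set as a block, within 12 and within 6 arrays were -0.79, -0.85 and -0.72 for sarcomere, -0.72, -0.70 and -0.70 for energy metabolism, and -0.205, -0.25 and -0.21 for excitation-contraction coupling. Glycolysis gave -0.37, -0.41 and -0.395, ER stress -0.141, -0.123 and -0.055, mitosis 0.52, 0.59 and 0.48, replication 0.217, 0.219 and 0.196, and fibroblast markers 0.285, 0.34 and 0.22, not passing within the 6 (adjusted p = 0.087).

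The other 17 lists did not pass at day 1, though single members did, and the neuromuscular junction passed with the array set as a block (-0.17, adjusted p = 0.0418). Myogenic regulators had 6 of 15 down and Pitx3 up (-0.10, adjusted p = 0.0581), fusion and adhesion 7 of 27 down and 4 up (-0.058, adjusted p = 0.20), and the neuromuscular junction 4 of 11 down, all of them acetylcholine receptor subunits, and Agrn up (-0.171, adjusted p = 0.161). Cell cycle exit had 3 of 18 down and 2 up (-0.043, adjusted p = 0.425), the progenitor list 8 of 23 down and 3 up (-0.058, adjusted p = 0.244), and the IGF axis 5 of 19 down and 6 up (0.033, adjusted p = 0.867). Extracellular matrix had 8 of 34 down and 10 up (0.047, adjusted p = 0.938), interferon response 3 of 24 down and 9 up (0.092, adjusted p = 0.20), and inflammation 4 of 13 down and 4 up (0.104, adjusted p = 0.693). For p53 targets 8 of 20 fell and 5 rose; their median (0.035) and mean (-0.084) differ in sign (adjusted p = 0.426). Immediate early genes had 3 of 22 down and 5 up (0.126, adjusted p = 0.166), heat shock proteins 7 of 17 down and 1 up (-0.156, adjusted p = 0.149), cholesterol synthesis 1 of 18 down and 3 up, 1 and 1 adjusted over the list alone (0.23, adjusted p = 0.382), and the RNAi machinery 1 of 12 down and 4 up (0.055, adjusted p = 0.317). Smooth muscle markers had 3 of 12 down and 4 up (0.055, adjusted p = 0.867), adipocyte markers 1 of 12 down and 3 up (0.065, adjusted p = 0.349), and bone cell markers 3 of 8 up (0.28, adjusted p = 0.172).

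**Figure D4:**
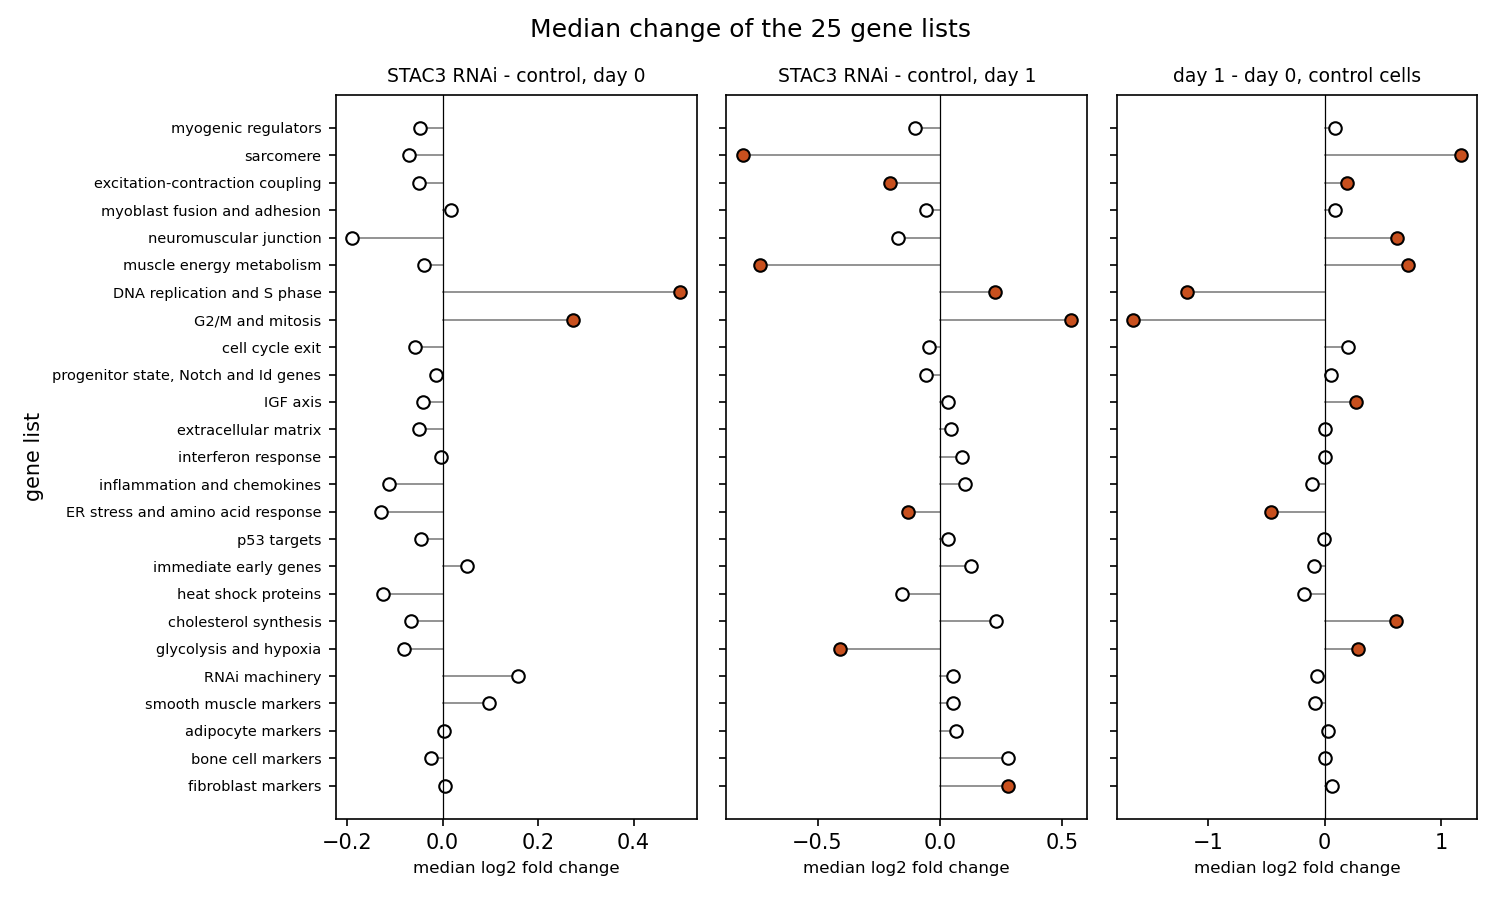
Median log2 fold change of the 25 gene lists for RNAi against control at day 0 and day 1 and for control differentiation. Filled points have a camera adjusted p below 0.05; replication shifts up at day 0, and muscle lists shift down at day 1.

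How does the day 1 effect relate to differentiation itself? Of the 29 sarcomere genes that rose in control cells 24 fell under RNAi at day 1, and 17 of the 29 still rose in RNAi cells, with a median of 0.43 against 1.305 in controls. In energy metabolism 11 of 12 such genes fell and 6 still rose (0.29 against 1.13). In excitation-contraction coupling 9 of 10 fell and 4 still rose (0.26 against 1.06). Picking genes that rose in control cells uses the same day 1 controls and widens these gaps. Over all measured members the medians in RNAi and control cells were 0.34 and 1.17 for sarcomere, 0.146 and 0.71 for energy metabolism, and 0.157 and 0.19 for excitation-contraction coupling. The means of that last list lie further apart, at 0.217 and 0.647. Over all probes 1384 that rose in control cells fell under RNAi, and 1004 that fell rose under RNAi. Lists that shared no samples and no effect would overlap in 530.7 and 561.1. Same-sign overlaps were 381 and 341, against 550.2 and 541.2 for such lists.

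These comparisons share the day 1 controls, which alone pulls them toward opposite signs. With the controls split so that none is shared, 65.8% of probes passing in differentiation had an RNAi change of the opposite sign (61.9 to 70.5 over 6 splits), with a slope of -0.297 (-0.353 to -0.266) and r of -0.368. Unsplit values were 68.0%, a slope of -0.331 and r of -0.414, and of all genes 60.9% had opposite signs. In 20 simulations with noise and shared controls alone the slope was -0.432, r was -0.467 and 65.2% of all genes had opposite signs, so the unsplit slope, r and share of all genes do not tell an effect from sharing. No simulated value was computed for the 68.0%. The covariance does differ, at -0.064 unsplit and -0.058 split against -0.00494 in the simulations.

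**Figure D5:**
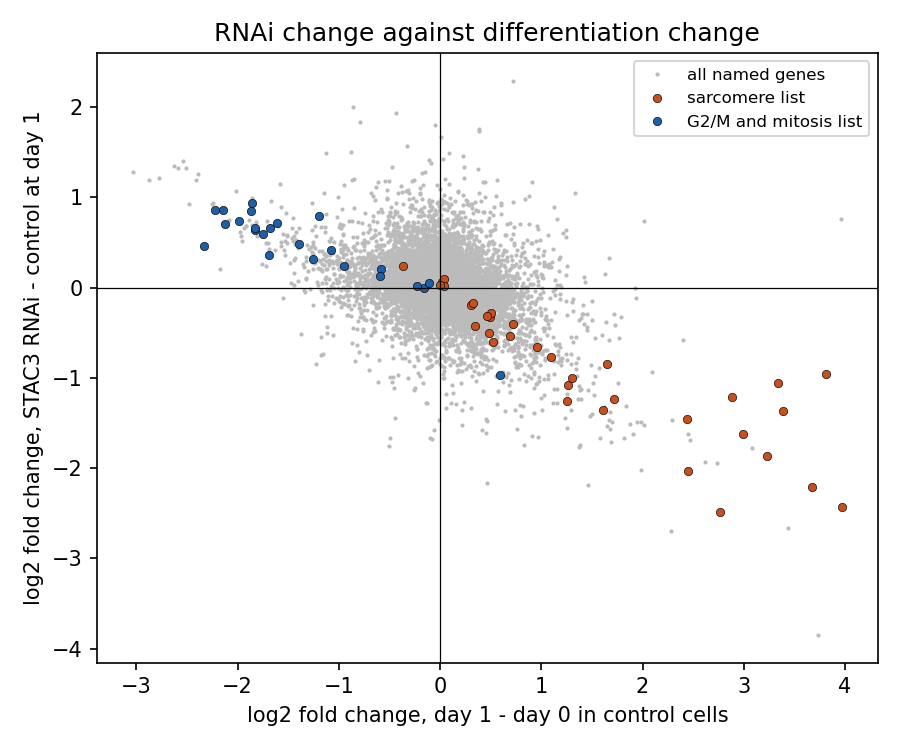
RNAi against control at day 1 (log2 fold change, vertical) over control differentiation (log2 fold change, horizontal) for all named genes in grey, sarcomere genes in orange and mitotic genes in blue. The coloured groups lie in opposite corners; the shared day 1 controls add to that slope.

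RNAi cells did change from day 0 to day 1. That comparison has 4 samples against 4 and the control one 4 against 3, so their counts of passing probes differ in power. In all 7628 probes passed, 3807 up and 3821 down (7875 with the array set as a block, 7087 within 12 arrays, 3003 within 6), against 6599 in control cells. Myog rose by 1.03 (SE 0.24), from a day 0 level under detection in 3 of 4 samples, and Cdkn1a by 0.36 (SE 0.08). Replication genes fell in 29 of 30 (-1.53, adjusted p = 8.72e-25; 0.0608 with an estimated correlation) and mitotic genes in 23 of 24 (-1.255, adjusted p = 4.22e-15; 0.0608 with an estimated correlation), counts that are unchanged adjusted over the list alone. Sarcomere genes rose in 17 of 34, 19 adjusted over the list alone, and Tpm3 fell (0.34, adjusted p = 0.00217, or 0.521 with an estimated correlation). Within the 6 arrays the shift was 0.082. The 1 RNAi day 0 sample there is replicate 4, whose sarcomere mean stands apart (-0.285 against -0.751 in the others), so that shift does not test the array sets. Cholesterol synthesis rose in 17 of 18, 18 adjusted over the list alone (0.78, adjusted p = 1.4e-06; 0.28 with an estimated correlation), the neuromuscular junction in 8 of 11, 9 adjusted over the list alone (0.61, adjusted p = 0.00217; 0.28 with an estimated correlation) and interferon genes in 12 of 24 with Isg15 down, 14 and 1 adjusted over the list alone (0.199, adjusted p = 0.0107; 0.28 with an estimated correlation). The IGF axis rose in 10 of 19 (0.26, adjusted p = 0.00816; 0.0608 with an estimated correlation) and fibroblast markers in 7 of 11 (0.39, adjusted p = 0.0107; 0.0608 with an estimated correlation), both unchanged when adjusted over the list alone. ER stress genes fell in 20 of 27 and Stc2, Nupr1 and Vldlr rose, 21 and 3 adjusted over the list alone (-0.45, adjusted p = 9.34e-06; 0.0608 with an estimated correlation). Heat shock genes fell in 8 of 17 and Bag3 and Hspb2 rose, 9 and 2 adjusted over the list alone (-0.157, adjusted p = 0.00816; 0.28 with an estimated correlation).

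Which effects of STAC3 RNAi differ between the days? The day 1 effect minus the day 0 effect passed for 865 probes, 411 above 0 and 454 under 0, of which 281 and 274 are named genes. Muscle genes gave the most negative differences: Pvalb at -3.57 (SE 0.44), Tnnc2 at -1.98 (SE 0.53), Mb at -1.76 (SE 0.41) and the muscle phosphoglycerate mutase Pgam2 at -1.71 (SE 0.31), with Fgf21 at -1.98 (SE 0.15). Pvalb and Pgam2 lie under the detection level in most RNAi samples of both days. The most positive were Fam180a at 2.24 (SE 0.17), Ugt1a10 at 1.72 (SE 0.43), Mgst1 at 1.49 (SE 0.29), Fam20a at 1.29 (SE 0.21) and Igfbp4 at 1.25 (SE 0.29, largest adjusted p = 0.0454). Ckm (-1.46, SE 0.24, adjusted p = 0.00313), Cdkn1a (-0.795, SE 0.12, adjusted p = 0.00183) and Stac3 (-0.60, adjusted p = 0.00982) passed as well. Stac3 is under detection in all RNAi samples, so its difference mainly restates the rise in controls. Ckm is under detection in both groups at day 0, so its difference mainly restates its fall at day 1. Myog (-1.27, SE 0.35, adjusted p = 0.054) and Myod1 (-0.60, SE 0.18, adjusted p = 0.0746) did not pass. The calls of Ugt1a10, Tnnc2, Mb and Igfbp4 are lost when some single samples are left out. With the array set as a block 1216 probes passed, within the 12 arrays 1098, and within the 6 arrays limma called 0, with 1358 there at an unadjusted p below 0.05. The count depends on single samples: it was 453 without control day 0 replicate 3, 470 without control day 0 replicate 2 and 555 without STAC3 RNAi day 1 replicate 2.

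By gene group the difference between days was negative for sarcomere (median -0.63, 7 of 34 passing, 19 adjusted over the list alone, adjusted p = 1.2e-12; 0.198 with an estimated correlation), energy metabolism (-0.48, 8 of 17, 9 adjusted over the list alone, adjusted p = 5.55e-08; 0.0515 with an estimated correlation) and replication (-0.23, 5 of 30, 10 adjusted over the list alone, adjusted p = 9.35e-07; 0.23 with an estimated correlation). The same holds for glycolysis (-0.26, 3 of 21 under 0 and 1 above, 8 and 1 adjusted over the list alone, adjusted p = 2.74e-05; 0.211 with an estimated correlation), excitation-contraction coupling (-0.169, 4 of 22, 6 adjusted over the list alone, adjusted p = 0.00132; 0.188 with an estimated correlation) and myogenic regulators (-0.14, none of 15, 4 under 0 and 1 above adjusted over the list alone, adjusted p = 0.0472; 0.176 with an estimated correlation). It was positive for mitosis (0.219, adjusted p = 0.0133; 0.503 with an estimated correlation), interferon response (0.137, adjusted p = 0.0133; 0.278 with an estimated correlation), immediate early genes (0.139, adjusted p = 0.0442; 0.455 with an estimated correlation) and cholesterol synthesis (0.30, adjusted p = 0.0257; 0.584 with an estimated correlation). Inflammation (0.32, adjusted p = 0.00116; 0.0769 with an estimated correlation), bone cell markers (0.37, adjusted p = 0.0121; 0.0769 with an estimated correlation) and fibroblast markers (0.325, 2 of 11, 7 adjusted over the list alone, adjusted p = 0.000278; 0.0354 with an estimated correlation) were positive too, and the fibroblast list alone kept its pass. In these 7 lists few members passed singly: Anln, Bub1b and Cdc20, with Ccnf under 0, for mitosis, Gbp2 and Ifi27 for interferon, Egr1 and Egr2, Csf1, Bglap2, and Pdgfra and Dpt. Adjusted over the list alone there were 4 above and 1 under 0 of 24 for mitosis, 6 of 24 for interferon, 5 of 13 for inflammation, 2 of 22 for immediate early genes, 0 of 18 for cholesterol synthesis and 3 of 8 for bone cell markers.

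Within block, 12 and 6 arrays these differences between days were -0.60, -0.53 and -0.57 for sarcomere, -0.47, -0.45 and -0.39 for energy metabolism, -0.25, -0.30 and -0.38 for replication, -0.23, -0.32 and -0.171 for glycolysis, and -0.158, -0.158 and -0.146 for excitation-contraction coupling. Fibroblast markers gave 0.33, 0.41 and 0.22, inflammation 0.305, 0.28 and 0.43, bone cell markers 0.34, 0.31 and 0.35, cholesterol synthesis 0.32, 0.31 and 0.31, and interferon 0.143, 0.135 and 0.123. Myogenic regulators (-0.145, -0.14 and -0.083) and mitosis (0.166, 0.133 and -0.015) lost their pass with the block and within the 12 arrays. Immediate early genes (0.116, 0.104 and 0.077) and interferon (adjusted p = 0.0652) lost it within the 12 arrays. Passes within the 6 arrays are not read here, since that set holds 1 control and 1 RNAi sample at day 0.

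Did the 2 days share an effect? Of the probes passing at day 0, 849 rose on both days (208 for independent lists) and 801 fell on both (173 for independent lists), while 13 and 16 passed with opposite signs. The comparisons share no sample, but both take their residual spread from 1 fit, so their calls are not fully independent. Across 10146 genes the changes had r of 0.679 (rank correlation 0.616). Timp2, Rnpepl1 and Gja1 are among the largest rises on both days, with no pass for a difference between days. Of the 20 genes with the largest day 0 changes 19 passed at day 1, the exception being E2f1.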

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

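The tests on histone genes and on proportion to the fall of Stac3 were thought of after the results had been seen. The rules for the other tests were written before their values were computed. The test of the control course is an exception. By its rule as first written the value counted against a delay, and the test was changed to undecided after that value was known. Values within the set of 12 arrays rest on the names of the authors' value table, because that set holds the 12 arrays whose names differ between the tables. At day 0 the set of 6 holds 1 control and 1 RNAi sample, so its day 0 calls borrow their spread from the day 1 samples, and its day 0 values (a replication median of 0.64, and 8 of the 20 genes of the last pattern passing) carry no weight here.

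Replication genes were higher in STAC3 RNAi cells at day 0, with a median of 0.50, though the camera call was lost with an estimated correlation (adjusted p = 0.159). A difference between the array sets was ruled against, since the median stayed above 0.25 within the 12 arrays (0.535). 1 sample out of place was ruled against too, as the lowest median with any day 0 sample left out was 0.372 (without control replicate 4). More cells in S phase could raise these genes. Replication-dependent histone genes had a median of 0.043, with 13 higher and 6 lower of 47. That median is the value of H2bc8, whose means (6.797 in controls, 6.84 in RNAi cells) lie under the detection level. Brighter members moved both ways: H2ac10 (0.49) and H2ac15 (0.58) rose, while H2bc4 (-0.61) and H2bc6 (-0.50) fell. The median therefore cannot tell more cells in S phase from more transcription per cell. Whether loss of Stac3 keeps myoblasts cycling is a hypothesis that counts of cells in each cycle phase would test.

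Muscle genes were lower in STAC3 RNAi cells at day 1, with a sarcomere median of -0.81, but the change was not confined to them. Mitotic genes rose in 19 of 24 (median 0.54). The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.312 for each). The means of fibroblast markers were higher in every RNAi sample (0.204 to 0.307) than in every control (-0.073 to -0.03), as were those of bone cell and adipocyte markers. The fibroblast list lost its camera pass with an estimated correlation (adjusted p = 0.261). The bone cell and adipocyte lists did not pass (camera adjusted p = 0.172 and 0.349). Shared day 1 controls were ruled against as the cause of the opposite direction to differentiation: with no control shared the highest slope over 6 splits was -0.266. A difference between the array sets was ruled against, as the sarcomere median was -0.853 within the 12 arrays and -0.72 within the 6. RNAi cells may simply be less advanced along the control course, which would move risen genes down and fallen genes up. Risen genes had medians of -0.183 to -0.123, but fallen genes 0.06 to 0.102, under the bound of 0.1 in 5 of 6 splits. By the rule as first written this counted against a delay. With the medians on both sides of the bound, a delay is left as neither shown nor excluded. That STAC3 is needed early in differentiation is a hypothesis, which a later time point or a second RNAi sequence would test, and a turn of RNAi cells toward other cell types was not tested and stays open, while fibroblast markers did not pass in control differentiation (median 0.068).

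The 20 genes with the largest day 0 changes, such as Rnpepl1, H2ax and Bcap29, are not known parts of excitation-contraction coupling. Within the 12 arrays 20 of 20 passed in the same direction. The genes were picked on largely the same samples as groups that do not overlap, so this does not test a difference between the array sets. Effects in proportion to the fall of Stac3 might be looked for as larger changes at day 1, where Stac3 fell 2.81 times as far on the log2 scale, but the median ratio of the day 1 to the day 0 change was 0.905 (from -0.121 to 1.32). The fall of Stac3 is known only as a lower bound, because RNAi samples are under detection, so effects of Stac3 and effects of the RNAi sequence on other transcripts cannot be told apart. Only 1 RNAi against STAC3 is named in the labels, and a second one was not tested.

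Chance was weighed by regrouping the samples. Of 35 regroupings of the day 0 samples 1, the real one, called as many probes (2298, highest other 2), and the same holds at day 1 (1 of 35, 6090, highest other 506). In control differentiation it was 1 of 35 (6599, highest other 3098) and in RNAi cells 1 of 35 (7628, highest other 0). For the difference between days 2 of 100 splits called at least as many (865, highest other 1404). The split with 1404 keeps the day 1 groups and moves 3 day 0 samples. These splits also break up the effects on each day, so they do not test the difference between days, and nothing is concluded from them. In the other 4 comparisons the real groups stood alone, which excludes chance at 1 in 20 only if the samples are independent. The labels do not say whether replicates came from separate transfections, so a chance difference between transfections is not excluded.

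Single samples standing apart from their group were looked for in 480 groups of named genes and lists, and 31 did, where chance alone sets apart about 1 in 20. Control day 0, with 3 samples, was not searched. STAC3 RNAi day 0 replicate 4 stood apart in Myog (7.14 against a mean of 6.77 in the others), Fstl1 (11.42 against 10.84), Mylpf (9.62 against 7.94), Pdlim3 (8.74 against 7.80), Tnni2 (7.90 against 7.22), Ccne2 (9.01 against 9.28), Tk1 (11.53 against 11.68) and Tead4 (7.44 against 7.66), and in the list means of sarcomere (-0.285 against -0.75) and fusion (-0.09 against -0.165). STAC3 RNAi day 1 replicate 4 did in Pvalb (7.42 against 6.785), Tnnc2 (9.86 against 8.62), Pgam2 (7.25 against 6.83), Csrp3 (7.11 against 6.83), Rbm24 (6.98 against 6.79), Tnni2 (9.74 against 8.71), Fbxo32 (9.13 against 8.90) and the sarcomere mean (0.49 against -0.071). STAC3 RNAi day 1 replicate 3 did in Aurka (8.999 against 8.77), Anln (10.55 against 10.29), Nfkbia (8.92 against 9.075) and Phgdh (8.48 against 9.24). STAC3 RNAi day 0 replicate 1 did in Pfkm (10.13 against 9.94) and the means of glycolysis (-0.001 against -0.191) and RNAi machinery (0.159 against 0.099), and replicate 2 in Fam180a (6.985 against 6.85). Among controls at day 1, replicate 1 did in Abhd17a (10.535 against 9.92) and Ccl9 (8.71 against 8.11), replicate 2 in the cholesterol mean (0.041 against 0.37), replicate 3 in Bub1b (8.06 against 7.74) and replicate 4 in Gja1 (10.42 against 11.30). The higher sarcomere means are not confined to RNAi cells or to 1 sample: replicate 4 has the highest sarcomere mean in all 4 groups (-0.262 and 1.29 in controls, -0.285 and 0.49 in RNAi cells at day 0 and day 1), and the highest means of excitation-contraction coupling and of the neuromuscular junction in all 4.

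The RNAi effect differed between days for 58 of 135 named genes, with adjusted p from 5.01e-06 to 0.0474. Some of these genes were named because they passed this comparison or lead a list that did, so that share is set partly by the choice. Over all probes 865 of 18408 passed (4.7%). Muscle genes had Pvalb -3.57, Tnnc2 -1.98, Mb -1.76, Pgam2 -1.71, Chrng -1.64, Actn3 -1.54, Ckm -1.46, Srl -1.38, Tnnt3 -1.29, Hrc -1.25, Csrp3 -1.12, Chrnd -1.01, Eno3 -0.91, Cox7a1 -0.88, Cox6a2 -0.71, Tmod1 -0.56, Jsrp1 -0.52 and Pfkm -0.48. Cell cycle genes had E2f1 -1.33, Cdkn1a -0.795, Ccne2 -0.62, Rrm1 -0.52, Ccne1 -0.46, Ccnf -0.25, Cdc20 0.79, Anln 0.75 and Bub1b 0.53, and the histone genes H2ac22 1.05, H2ac7 0.99, H2ac20 0.81 and H2ac15 0.70. Secreted and signalling genes had Fam180a 2.24, Fam20a 1.29, Igfbp4 1.25, Fstl1 0.86, Csf1 0.77, Dpt 0.91, Pdgfra 0.43, Bglap2 0.69, Tgfbr1 -0.38, Igfbp2 -1.09 and Fgf21 -1.98. Egr2 had 1.02, Egr1 0.77, Gbp2 0.65, Ifi27 0.32 and Ndrg1 0.695. Enzymes and others had Ugt1a10 1.72, Mgst1 1.49, Acot1 1.06, Nme7 -1.13, Vldlr -1.01, Psat1 -0.98, Asns -0.59, Pkm -0.57, Tpi1 -0.64, Gapdh -0.39 and Stac3 -0.60. By list it differed for 13, of which only fibroblast markers kept their pass with an estimated correlation, and myogenic regulators and mitosis lost theirs with the array set as a block: sarcomere -0.63, energy metabolism -0.48, glycolysis -0.26, replication -0.23, excitation-contraction coupling -0.169, myogenic regulators -0.14, mitosis 0.219, interferon 0.137, inflammation 0.32, immediate early genes 0.139, cholesterol synthesis 0.30, bone cell markers 0.37 and fibroblast markers 0.325.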

How the results depend on the processing

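The settings with array sets, the filter at 9 arrays and the 6 arrays with matching names were chosen after the data had been seen. The other settings were laid down beforehand.

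Limits first. Each group holds 3 or 4 samples of 1 cell line, and the labels name 1 RNAi against STAC3. Signals near background are compressed in the authors' values, so fitted folds of dim genes are too small, and the falls of Stac3 are given as bounds against the detection level. Whether equal replicate numbers pair control and RNAi samples is unsettled: after removing group means, samples of equal number correlated at 0.08, 0.20 and 0.49 at day 0 (own number the best match for 1 of 3) and at 0.39, -0.05, 0.24 and 0.37 at day 1 (3 of 4). Replicate 4 has the highest sarcomere mean in all 4 groups. The labels do not state a pairing, and the report treats samples as unpaired. A filter on detection in every array of a group and a block for the chip were not run, because column names give neither securely. The causes of the moves listed here were not tested unless stated.

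The tables differ in the names of 12 columns. The repeat arrays argue against the names of the non-normalized table: by those names the partner comes 12th, 4th and 17th, and by the value table it comes 1st each time. They speak for the columns of their partners only, and the rest of the 12 names were not checked this way. The fit first laid down, on the non-normalized table by column name, called 0 probes at day 0, day 1, for the difference between days and for control differentiation with background correction (neqc), with none, and with median scaling. At an unadjusted p below 0.05 these were 924, 447, 993 and 108 probes with neqc, 946, 405, 1050 and 72 without correction, and 1980, 178, 1209 and 72 with median scaling. In RNAi cells it called 623, 821 and 330 between days. Stac3 was -0.33, -0.186 and -0.44 at day 0 and -0.91, -0.48 and -0.72 at day 1, none passing. Reversal slopes turned to 0.42, 0.48 and 0.45. Agreement between days fell to 0 probes with r of -0.156, -0.195 and -0.168, so signs changed. Lists called were 8, 8 and 5 at day 0, 5, 5 and 5 at day 1, 5, 5 and 6 for the difference between days, 6 with neqc in control differentiation, and 6 and 6 with the first 2 settings in RNAi cells. Of named genes 12 of 29 kept their sign at day 0, 52 of 54 at day 1, 25 of 41 for the difference between days and 47 of 48 in control differentiation. The share of opposite sign among probes passing in control differentiation could not be computed there, with 0 calls. On the 6 arrays whose names match in both tables, the day 1 comparison on raw intensities (2 against 2 samples) called 1415, 2224 and 1666, of which 1355, 2156 and 1579 also passed in the report and none had the opposite sign. Those 6 arrays cannot speak for the other 12.

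Within the set of 6 arrays alone 9 probes passed at day 0, 1929 at day 1, 0 for the difference between days (1358 at an unadjusted p below 0.05), 2108 in control and 3003 in RNAi cells. There Stac3 at day 0 was -0.54, and the difference between days for mitosis was -0.015 in place of 0.219. Both rest on 1 sample of each group at day 0. Within the 12 arrays 10 of 172 calls on named genes and 4 of 43 list calls were lost. Losses within the 6 arrays are not counted here, since that set holds 1 sample of each group at day 0. Myogenic regulators in control cells (0.136) passed within the 12 arrays though not over all arrays. Within the 6 arrays the shifts were -0.19 for glycolysis at day 0 and -0.137 for heat shock in the difference between days. In RNAi cells they were -0.111 for smooth muscle and 0.38 for bone cell markers. Within the 12 arrays Stac3 at day 0 was -0.295 (adjusted p = 0.0671). With repeat arrays left out it was -0.29 (adjusted p = 0.0506).

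Array weights raised the calls to 3456 at day 0 and 1530 for the difference between days. With 1 probe per gene, which tests fewer probes by construction, there were 3865 at day 1, 4071 in control and 4604 in RNAi cells. With the replicate block the counts were 2387 at day 0, 6363 at day 1, 1102 for the difference between days, 6679 in control and 7942 in RNAi cells, and 6 lists passed at day 0 in place of 2 (6 also with the block by day), adding energy metabolism, inflammation, ER stress and glycolysis, all downward.

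Camera with an estimated correlation called 0 lists at day 0, 0 at day 1, 1 for the difference between days, and 0 in control and 0 in RNAi cells, where the preset called 2, 8, 13, 10 and 10. The estimated setting also takes fewer degrees of freedom, so these losses need not all come from correlation between genes. The rotation test fry, which does not rank a list against other genes, called 4 at day 0, 19 at day 1, 10 for the difference between days, 18 in control and 22 in RNAi cells. For the difference between days it lost mitosis, immediate early genes and cholesterol synthesis (adjusted p = 0.202, 0.147 and 0.321).

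Leaving out each sample in turn gave 1480 to 2565 probes at day 0 (1480 without control day 0 replicate 4) and 453 to 1084 for the difference between days. The lowest there were 453 without control day 0 replicate 3, 470 without control day 0 replicate 2 and 555 without STAC3 RNAi day 1 replicate 2. Stac3 at day 0 ran from -0.37 to -0.28. Its pass was lost without control day 0 replicate 2 (-0.34, adjusted p = 0.0567) or 4 (-0.28, adjusted p = 0.101) and without STAC3 RNAi day 0 replicate 1 (-0.32, adjusted p = 0.0525) or 2 (-0.316, adjusted p = 0.0545). Lists called at day 0 ran from 2 to 5 (5 without STAC3 RNAi day 0 replicate 1). Of 172 calls on named genes 16 were lost without some sample, among them Cdkn1a at day 0 and Myod1 at day 1. Of 43 list calls 7 were lost, among them ER stress at day 1 without control day 1 replicate 3 and glycolysis in control cells without control day 0 replicate 2. The samples whose absence weakened most calls were control day 0 replicates 2 and 3, in the smallest group.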

Other observations

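The gene families here were chosen by symbol after the data had been seen, and no test of an explanation was planned for them. They were tested as the lists were, 1 adjustment over the families of a comparison.

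At day 1 the complex I genes of the respiratory chain fell in 20 of 34 under STAC3 RNAi and none rose (median -0.24, camera adjusted p = 6.72e-06; adjusted p = 0.0628 with an estimated correlation), Ndufb10 at -0.633, Ndufb9 at -0.632, Ndufa4 at -0.54 and Ndufs3 at -0.53. Mitochondrial ribosomal genes fell in 26 of 72 and rose in 6 (-0.124, adjusted p = 0.00059; 0.0628 with an estimated correlation). Cytosolic ribosomal genes rose in 22 of 55 and fell in 2 (0.163, adjusted p = 0.000206; 0.163 with an estimated correlation). The difference between days was -0.226 for complex I (adjusted p = 0.0348 with an estimated correlation) and -0.12 for mitochondrial ribosomal genes (0.0348), so both kept their pass there, and 0.167 for cytosolic ribosomal genes (0.0575).

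Histone genes rose in 24 of 47 at day 1 and fell in 6 (0.157, adjusted p = 0.000206; 0.109 with an estimated correlation). The largest rises were H2A genes such as H2ac10 (1.40), H2ac7 (1.35) and H2ac24 (1.32), and H3 and H4 genes such as H4c1 (0.65) rose too. The 6 falls were H2B genes, such as H2bc6 (-0.50) and H2bc4 (-0.445), though the H2B gene H2bc21 rose (0.36). At day 0 fewer passed, 13 up and 6 down, with H2ac21 at 0.71, H2ac12 at 0.61, H2bc4 at -0.61 and H2bc6 at -0.50, while H2ac22 (0.16, adjusted p = 0.52) did not pass and H1f2 (-0.42) passed only then. The members are nearly identical in sequence, so how far their probes tell them apart was not tested.

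In control differentiation proteasome genes fell in 21 of 33 and 1 rose (-0.25, adjusted p = 8.45e-05; 0.00825 with an estimated correlation). The cytosolic chaperonin fell in 6 of 8 (-0.34, adjusted p = 0.00471; 0.0281 with an estimated correlation), with Cct6a at -0.53 and Tcp1 at -0.44. Histone genes fell in 27 of 47 and rose in 9 (-0.27, adjusted p = 6.1e-07; 0.0281 with an estimated correlation). Mitochondrial ribosomal genes fell in 26 and rose in 3 (-0.156; 0.0298 with an estimated correlation). These 4 families kept their pass with an estimated correlation.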
